A study of Nicotiana tabacum with 6 samples.

How the data were processed

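Total RNA from young leaves of tobacco variety NC82 at the seedling stage, kept at 4 °C for 24 h, was made into paired-end TruSeq libraries and sequenced, per the labels' protocols. There were 6 libraries, 3 from plants overexpressing NtPhyA and 3 from wild type, grouped by the labels. Per the submitters' processing notes, HISAT2, StringTie and RSEM were used, and their versions, settings and genome build are not given in the sources used here. The deposited values, 1 table per plant material, are a normalized abundance per gene model and library. The labels do not say whether the authors' unit is TPM or FPKM, and the library totals differ. Nothing says whether the 2 tables were normalized together, so every level set across them assumes that values per library are comparable, which other scalings probed. Both tables list the same 69500 models, of which 19827 are described as unknown and 0 have a gene symbol. The authors' group means in the tables were not used. No genome coordinates are given for the models.

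No read counts were used here, so the count test fixed beforehand was replaced by the form fixed for normalized values. Values were transformed to log2(value + 1), and the 17962 models with a mean of at least 1 over the 6 libraries were fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust options, 4 residual degrees of freedom). The model held the group alone. Calls were made at a Benjamini-Hochberg adjusted p below 0.05, with log2 differences given as overexpression minus wild type on the log2(value + 1) scale, which understates changes of genes with low values. Relative depth was estimated from the value of 1 read in models seen in few libraries. The method was tested on simulated data of 30000 models, with a largest error of 0.000221 log2 units.

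In all, 41 gene lists were written as text patterns on gene descriptions before the data were examined, as were the tests and most of the settings compared with them. Of these, 35 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 35 lists. The pattern of the phytochrome list excluded the described phytochromes by mistake, so phytochrome models were found by that word in the description instead. Descriptions that also held the letters regulat or interact were left out. Another 14 lists were worded after the descriptions and first results were seen. Single values of 3 against 3 libraries were compared by exact two-sided permutation of the libraries, whose smallest p is 0.1.

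The rule for named genes took expressed models described as phytochrome A to E, the called genes with the largest changes at a mean of at least 5 with no overlap between groups, called members of lists and the most abundant called genes. Since 1 gene was called, below that mean, genes that did not pass were also named by smallest unadjusted p, by list and by highest mean, chosen after their values were seen.

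The fit was tested on simulated data with the means and spreads of the 17962 models and 200 changed models. At 2-fold and 4-fold it recovered 0%, at 8-fold 75% and at 16-fold 83%. In a simulation of the list test with genes drawn independently, 1 shifted list was called and 0 of the other 34. Estimated correlations in the real lists reached 0.592 (starch metabolism), so this simulation could not show false calls made by the preset correlation of 0.01. The alternatives were a pseudocount of 0.1, no filter, a value of at least 1 in at least 3 libraries, a minimum log2 difference of 1, an adjusted p below 0.01, replicate number as a block, and leaving out each library. Added after seeing the data were 5 scalings, a surrogate variable, library weights, whose estimation did not converge, and leaving out both replicates numbered 3. The same settings were run on the 14 added lists.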

Results

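Gene expression was measured in young leaves of tobacco (Nicotiana tabacum, variety NC82) at the seedling stage, after 24 h at 4 °C. The 6 RNA-seq libraries form 2 groups of 3: plants overexpressing the gene NtPhyA and wild-type plants. The series title places the comparison in the context of cold resistance. All 6 libraries come from chilled leaves, so the comparison is between the plant materials and holds no measure of the response to cold itself. Nothing in the labels says that the replicates came from separate plants, and p-values then measure only the spread between these libraries, which may be technical.

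Each library lists a normalized abundance for the same 69500 gene models. The values sum to 460319, 450972 and 568208 in wild-type replicates 1, 2 and 3, and to 475581, 451603 and 440137 in overexpression replicates 1, 2 and 3. Read totals are not given in the sources used here. The step that 1 read makes in the low values put the deepest library at 1.34 times the depth of the shallowest. Between 31369 and 33469 models per library were above 0, and 17962 models with a mean abundance of at least 1 over the 6 libraries were tested. Genes are named below by the description and the model identifier of the files, which pair no gene symbols with the models.

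Phytochromes are red and far-red light receptors, and the transgene carries the name of one of them. Higher abundance of phytochrome transcripts was not detected in the overexpression libraries. With descriptions of regulation or interaction left out, 10 gene models had the word phytochrome in their description. They summed to 5.19 ± 3.94 in wild-type leaves and 5.98 ± 3.28 in overexpression leaves (SD, n = 3 each, exact two-sided permutation p = 0.8). The 5 models described as phytochrome A/B/C/D/E, a description that does not single out A, summed to 1.95 ± 0.78 and 1.96 ± 0.86 (SD, n = 3 each; exact two-sided permutation p = 1). Of these 5, Nitab4.5_0009346g0010 alone reached the abundance minimum, at 1.75, 0.81 and 0.71 in wild type and 1.6, 0.83 and 0.58 under overexpression. Its log2 difference was -0.06 ± 0.35 (SE; limma adjusted p = 0.999), with a 95% confidence interval from -0.89 to 0.77. A further phytochrome-domain model, Nitab4.5_0016503g0010, was at 2.67 ± 3.03 in wild type and 3.53 ± 2.70 under overexpression (SD, n = 3), with a limma adjusted p of 0.999. Of the 10 models, 4 were listed at 0 in all 6 libraries. Which model corresponds to the transgene is not given in the sources used here, and reads of a transgene that differs from the listed models need not be counted in them. These values therefore do not check the labels.

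**Figure D1:**
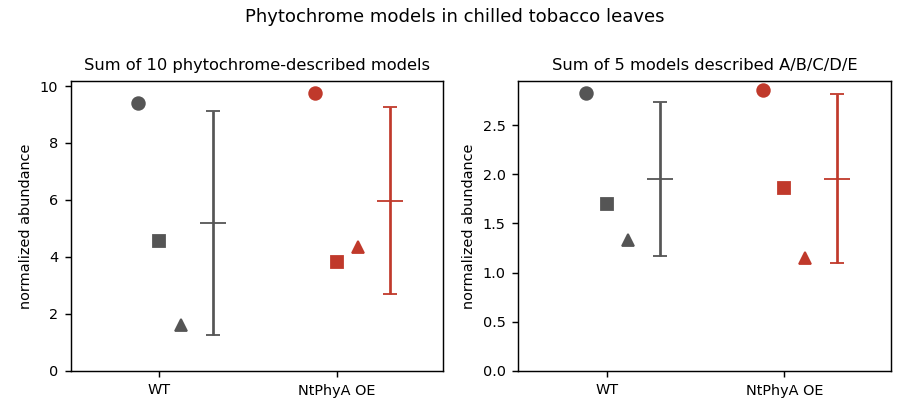
Summed normalized abundance (vertical axis) of the 10 phytochrome-described models (left) and of the 5 models described as A/B/C/D/E (right), in wild-type (grey) and NtPhyA overexpression (red) libraries. Circles, squares and triangles are replicates 1, 2 and 3, and bars show mean ± SD; the group means are 5.19 and 5.98 on the left and 1.95 and 1.96 on the right.

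Across all tested genes, 1 passed the threshold and it was higher in the overexpression leaves. Nitab4.5_0000002g0390, a ubiquitin-conjugating enzyme E2, which hands ubiquitin on to target proteins, was listed at 0 in the 3 wild-type libraries and at 7.22, 10.42 and 9.20 in the 3 overexpression libraries (limma adjusted p = 0.046). It is singled out after its values were seen. A 0 in these files may be a failed estimate or a true absence, which was not checked in the reads. The 828 tested models for ribosomal proteins, proteasome subunits and ubiquitin-conjugating enzymes include this gene. Of them, 19, again with this gene, were listed at 0 in some library and at 5 or more in another. That count does not tell the 2 readings apart. The call was lost when any 1 of the 6 libraries was left out, with adjusted p between 0.207 and 0.881, while the log2 difference of 3.30 stayed between 3.195 and 3.432. Over all alternatives the adjusted p ranged from 0.0437 to 0.886, apart from 0.000826 with library weights whose estimation did not converge. No gene passed in the other direction, and the next smallest adjusted p was 0.142. At an unadjusted p below 0.05 limma gave 507 genes, 264 higher and 243 lower, where 898 would be expected by chance. The 3 values of each group did not overlap in 1413 genes, 7.87% of those tested, against 10% by chance. When known changes were put into the real overexpression libraries for 200 genes at a time, none of the 2-fold or 4-fold changes was recovered, and 50.2% of the 8-fold and 67.4% of the 16-fold changes were. With 200 changed genes, differences of 4-fold or less in single genes were therefore not detectable here. The limit with more changed genes was not tested, and the adjusted p depends on their number.

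The genes below did not pass the adjusted threshold. Because the rule fixed for named genes takes called genes, they were chosen after their values were seen, by the smallest unadjusted p among described genes with a mean abundance of at least 5 and no overlap between groups. All of them had a limma adjusted p of 0.999. Among those with lower values under overexpression, a gibberellin-regulated protein, Nitab4.5_0000283g0170, was at 17.8 ± 7.8 in wild type and 4.89 ± 1.31 under overexpression (SD, n = 3). It was the only member of the 13-gene gibberellin list called when adjusted over the list alone, and no member of that list was called over all genes. The list itself went the other way, with 9 of 13 members higher and a mean log2 difference of 0.32 (camera adjusted p = 0.0653). That difference was 0.17 without overexpression replicate 1 and 0.52, with a call, without overexpression replicate 3. An ABA/WDS-induced protein, Nitab4.5_0002764g0010, of a family named for induction by abscisic acid and water deficit, was at 118 ± 38 and 41.6 ± 12.4. A 2-oxoglutarate-dependent dioxygenase, Nitab4.5_0000119g0140, was at 35.2 ± 6.8 and 4.57 ± 4.39, and cytochrome c oxidase subunit VIa, Nitab4.5_0026287g0010, at 19.0 ± 6.3 and 4.73 ± 1.92. A pleckstrin homology domain protein, Nitab4.5_0008493g0020, was at 80.7 ± 25.7 and 32.7 ± 3.0, and an OB-fold nucleic acid-binding protein, Nitab4.5_0009592g0010, at 13.1 ± 3.7 and 5.45 ± 0.57.

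Among those with higher values under overexpression, inositol oxygenase, Nitab4.5_0000300g0140, was at 3.24 ± 0.80 in wild type and 10.2 ± 3.1 under overexpression (SD, n = 3). A PAS domain protein, Nitab4.5_0002291g0030, was at 28.8 ± 7.0 and 67.4 ± 12.3, and a sterol reductase of the ERG4/ERG24 family, Nitab4.5_0000380g0100, at 3.80 ± 0.90 and 9.02 ± 1.04. A JmjC domain protein, Nitab4.5_0000175g0140, was at 2.94 ± 1.08 and 7.83 ± 1.44. A phosphate permease, Nitab4.5_0001005g0050, was at 17.2 ± 5.2 and 38.6 ± 6.5, and a histone H4, Nitab4.5_0005525g0080, at 8.89 ± 5.96 and 34.1 ± 16.1. The smallest unadjusted p after that of the ubiquitin-conjugating enzyme among the genes named from the lists belonged to a LEA-14 protein, Nitab4.5_0003681g0020, at 1.43 ± 0.26 in wild type and 7.30 ± 2.51 under overexpression, with a limma adjusted p of 0.999.

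The gene lists for cold and dehydration that were fixed beforehand showed no call. Dehydrins and late embryogenesis abundant (LEA) proteins accumulate in plant tissue under cold and drought. Of the 73 tested members, 47 were lower and 26 higher under overexpression. The mean log2 abundance of the list was 4.11 ± 0.29 in wild type and 3.88 ± 0.04 under overexpression (SD, n = 3). Exact two-sided permutation gave p = 0.1, the smallest that 3 against 3 allows. Of the 35 lists, 3 reached this p, which each list reaches by chance with a probability of 0.1. The dehydrin and LEA difference of -0.23 was -0.06 without wild-type replicate 3 and -0.32 to -0.21 without any other. The camera test with the preset correlation gave an adjusted p of 0.172, and the adjusted p was 0.74 with an estimated correlation. The most abundant dehydrin, Nitab4.5_0000588g0250, was at 10715 ± 2428 in wild type and 8638 ± 681 under overexpression (limma adjusted p = 0.999), among the highest values of any model. The list meant for CBF cold regulators did not match the DREB-type CBF factors of the cold response. It matched histone-fold CBF/NF-Y factors and 4 models described as CBF1-interacting co-repressors, a name that does not tie them to the cold response. Its 20 members gave a camera adjusted p of 0.34, and its member with the smallest p was an NF-Y subunit B, Nitab4.5_0006039g0010, at 7.86 ± 0.91 and 13.8 ± 2.4. Fatty acid desaturases and phospholipases D (32 members, camera adjusted p = 0.0653), antioxidant enzymes (38 members, 0.328), glutathione S-transferases (58 members, 0.148), proline and polyamine enzymes (26 members, 0.427), soluble sugar enzymes (21 members, 0.172) and heat shock proteins and chaperones (242 members, 0.328) were not called either. Leaving out 1 library brought a call for desaturases and phospholipases D (0.22 without wild-type replicate 2, 0.16 without overexpression replicate 2) and for glutathione S-transferases (-0.29 without wild-type replicate 1). Of the lists worded after the first results, 2 linked to cold were called with the preset correlation and not with an estimated one. Dehydrins alone had 7 of 7 members lower (mean log2 difference -0.87, camera adjusted p = 0.00141; 0.000337 to 0.57 over the alternatives), and -0.38 with the call lost without overexpression replicate 3. AP2/ERF factors were lower by 0.18 (adjusted p = 0.0486; 1.81e-05 to 0.804 over the alternatives). Their call was lost without wild-type replicate 3 (0.00191), overexpression replicate 1 (-0.01) or overexpression replicate 2 (-0.185). A fatty acid desaturase with a cytochrome b5 domain, Nitab4.5_0000200g0080, was at 34.5 ± 3.2 in wild type and 56.1 ± 7.5 under overexpression, and an aquaporin, Nitab4.5_0000181g0120, at 76.9 ± 8.2 and 29.2 ± 18.5, both with a limma adjusted p of 0.999.

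Of the 35 lists tested, 10 passed the camera test with the preset correlation, 7 toward higher and 3 toward lower values under overexpression. None of the 10 calls held with an estimated correlation, where the adjusted p was 0.5 or more, and none was called by fry, which asks whether the genes of a list move one way (smallest p over the lists = 0.0904). No list had a member called over all genes, and the gibberellin list alone had a member called when adjusted over the list alone. The list of dividing-cell genes had 74 of 90 members higher under overexpression. It holds mostly histones (26 H2A, 19 H2B, 14 H4 and 12 H3), beside 10 kinesins and a few replication proteins. Its mean log2 abundance was 3.52 ± 0.13 in wild type and 4.00 ± 0.39 under overexpression (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible), with a camera adjusted p of 6.14e-12 and an adjusted p of 0.692 with an estimated correlation. The mean log2 difference of 0.49 fell to 0.28 without overexpression replicate 1, with the preset call kept. The unadjusted preset camera p of this list was 1.75e-13 for the real groups. Groupings of the 6 libraries that mix the plant materials gave it values from 8.06e-08 to 0.95, among them 1.79e-07 and 7.08e-06. Core histones, which package DNA, made up 0.516 ± 0.026% of the summed abundance in wild type and 0.686 ± 0.142% under overexpression (SD, n = 3; exact two-sided permutation p = 0.1). Examples are a histone H4, Nitab4.5_0003969g0050, at 8.44 ± 2.74 and 31.6 ± 20.01, and a histone H2A, Nitab4.5_0000070g0160, at 14.2 ± 1.8 and 28.5 ± 9.97. Histones and ribosomal proteins are families of near-identical copies, and how the counting divided reads between copies is uncertain. The 24 members of the cytosolic ribosome list were all lower under overexpression, with mean log2 abundances of 6.04 ± 0.17 and 5.75 ± 0.11 (SD, n = 3; exact two-sided permutation p = 0.1), a camera adjusted p of 0.000343 and an adjusted p of 0.711 with an estimated correlation. Their mean log2 difference of -0.28 was -0.18 without wild-type replicate 3, with the preset call kept. One of them, ribosomal protein L18a in model Nitab4.5_0001655g0060, was at 101 ± 22 in wild type and 64.4 ± 8.4 under overexpression.

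Genes of photosynthesis and starch were among the lists with higher values under overexpression. The light-harvesting and photosystem list had 134 of 182 members higher (camera adjusted p = 0.00902; adjusted p = 0.74 with an estimated correlation), although 34 of its members matched the word plastocyanin, mostly secreted plastocyanin-like copper proteins. Chlorophyll synthesis had 14 of 18 members higher (adjusted p = 0.0138; 0.711 with an estimated correlation) and starch metabolism 18 of 21 (adjusted p = 0.000523; 0.711 with an estimated correlation). A starch phosphorylase, Nitab4.5_0000454g0020, was at 29.5 ± 14.4 in wild type and 52.5 ± 6.0 under overexpression. A light-dependent protochlorophyllide reductase, Nitab4.5_0009946g0010, was at 0.683 ± 0.468 and 5.49 ± 4.72. Its overexpression values were 9.75, 6.31 and 0.42 in replicates 1, 2 and 3, and replicate 3 lay within the wild-type range of 0.19 to 1.12. The list meant for organelle-encoded genes, 42 of 58 members higher (adjusted p = 0.045; 0.74 with an estimated correlation), holds mostly PsbP, PsbQ and other photosystem proteins that the nuclear genome encodes. The exact two-sided permutation p of the list scores was 0.8 for light harvesting and for the organelle list, and 0.5 for starch and for chlorophyll synthesis. All 4 calls depended on single libraries. The mean log2 difference of the light-harvesting list, 0.23, became -0.08 without wild-type replicate 3 and -0.18 without overexpression replicate 1, and its call was also lost without wild-type replicate 2 (0.16). That of the organelle list, 0.17, became -0.07 and -0.15 without the same 2 libraries, and its call was also lost without wild-type replicate 2 (0.135) or overexpression replicate 2 (0.115). Starch, at 0.415, lost its call without wild-type replicate 3 (0.08) or overexpression replicate 1 (0.21), as did chlorophyll synthesis, at 0.41 (0.13 and 0.17). Without wild-type replicate 1 or overexpression replicate 3 the differences rose to 0.60 and 0.69 (light harvesting), 0.45 and 0.54 (organelle), 0.72 and 0.66 (starch) and 0.65 and 0.66 (chlorophyll). The number of lists called was 4 without wild-type replicate 3 and 6 without overexpression replicate 1.

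The receptor kinase list had 21 of 26 members higher (camera adjusted p = 0.000523, and 0.5 with an estimated correlation). Its members matched only the words wall-associated receptor (15) or receptor-like serine (11). Their mean log2 abundances were low, at 1.90 ± 0.19 in wild type and 2.19 ± 0.25 under overexpression (SD, n = 3). The glandular trichome list, which is made of terpene synthases, had 16 of 20 members higher (camera adjusted p = 0.00531, and 0.692 with an estimated correlation). The receptor kinase difference of 0.29 log2 units fell to 0.15 without overexpression replicate 3, with the call lost. The trichome difference of 0.39 fell to 0.06 without overexpression replicate 3 and 0.24 without wild-type replicate 1, both with the call lost, and rose to 0.72 without overexpression replicate 1. A terpene synthase, Nitab4.5_0009618g0010, was at 47.4 ± 3.0 in wild type and 70.6 ± 19.2 under overexpression. List scores gave an exact two-sided permutation p of 0.3 for receptor kinases and 0.4 for the trichome list. The jasmonate list had 17 of 25 members lower (adjusted p = 0.0273; 0.692 with an estimated correlation), and the circadian clock list 11 of 15 (adjusted p = 0.0273; 0.692 with an estimated correlation). These lists share 13 members, all TIFY proteins, a family that includes the JAZ repressors of jasmonate signalling. The circadian list therefore says little about clock genes. The jasmonate and circadian list scores each gave an exact two-sided permutation p of 0.4. Both calls were lost without wild-type replicate 2, wild-type replicate 3 or overexpression replicate 1. The jasmonate difference of -0.36 was then -0.36, -0.17 and -0.19, and -0.55 without wild-type replicate 1; the circadian difference of -0.475 was then -0.59, -0.16 and -0.26. A TIFY protein, Nitab4.5_0000201g0130, was at 44.9 ± 10.9 in wild type and 18.5 ± 7.7 under overexpression. Allene oxide cyclase, Nitab4.5_0004118g0110, an enzyme of jasmonate synthesis, was at 151 ± 63 and 77.8 ± 2.6. Its value in wild-type replicate 1, 77.73, lay within the overexpression range of 75.97 to 80.82. Lists for light signalling, auxin, cytokinin, pathogenesis-related proteins, WRKY, NAC and MYB factors, calcium signalling, cell wall enzymes and aquaporins passed no test. Neither did those for ubiquitin ligases, phenylpropanoids, carbon fixation, phloem, senescence and flowers, or a guard cell list that matched stomatin proteins. The 11 light signalling members matched the words cryptochrome (9) or FAR1 (2), so that list says little about other genes of light signalling. Of the 89 pathogenesis-related members, 68 matched proteinase inhibitor. Leaving out 1 library brought a call for carbon fixation (0.25 without wild-type replicate 1), aquaporins (-0.41 and -0.30 without overexpression replicates 1 and 2) and senescence (-0.52 and -0.35 without the same 2). It also did so for WRKY factors, toward lower values and against their camera direction with all libraries (-0.26 without overexpression replicate 3). In the auxin, WRKY and carbon fixation lists the camera direction was higher while the mean log2 difference was negative, in the phloem list it was lower while the mean was positive, and in the cell wall list it was higher while the median was negative.

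Libraries of the same plant material differed from each other as much as the plant materials did. Pearson correlations of log2 abundance averaged 0.898 within groups (0.831 to 0.937) and 0.905 between groups (0.824 to 0.948). The first principal component held 48.7% of the variance and placed overexpression replicate 1 and wild-type replicate 1 at one end and both replicates 3 at the other. The group difference held 16.8% of the variance, where 20% would be expected with no effect.

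**Figure D2:**
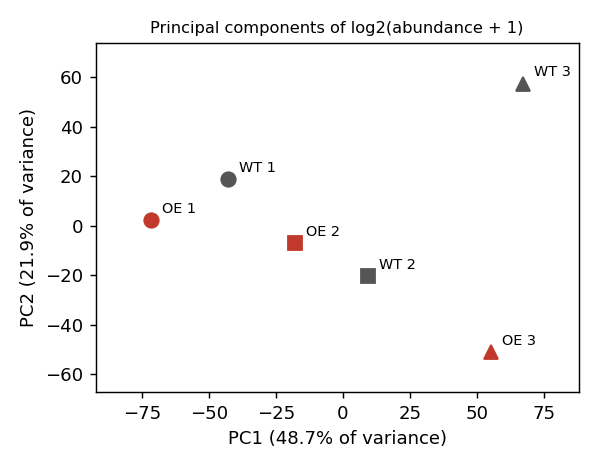
First and second principal components (48.7% and 21.9% of variance) of log2(abundance + 1) over 17962 gene models, for wild-type (grey) and NtPhyA overexpression (red) libraries. Each point is 1 library; the first component spreads libraries within both groups.

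The spread within groups was large for photosynthesis. The small subunit of Rubisco, the carbon-fixing enzyme, made up 4.80%, 2.69% and 1.15% of the summed abundance in wild-type replicates 1, 2 and 3 and 6.17%, 4.13% and 2.70% in overexpression replicates 1, 2 and 3 (exact two-sided permutation p = 0.4 for the group difference). The most abundant Rubisco small subunit model, Nitab4.5_0002207g0050, ranged from 4279 to 14600 in wild type and from 8902 to 18789 under overexpression. Antenna and photosystem proteins made up 3.62 ± 1.5% in wild type and 4.48 ± 2.18% under overexpression (SD, n = 3; exact two-sided permutation p = 0.6). The other models with the highest mean values, among them a metallothionein, a translationally controlled tumour protein, LEA-5 (Nitab4.5_0002820g0100) and PsbR proteins, had a limma adjusted p of 0.999.

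**Figure D3:**
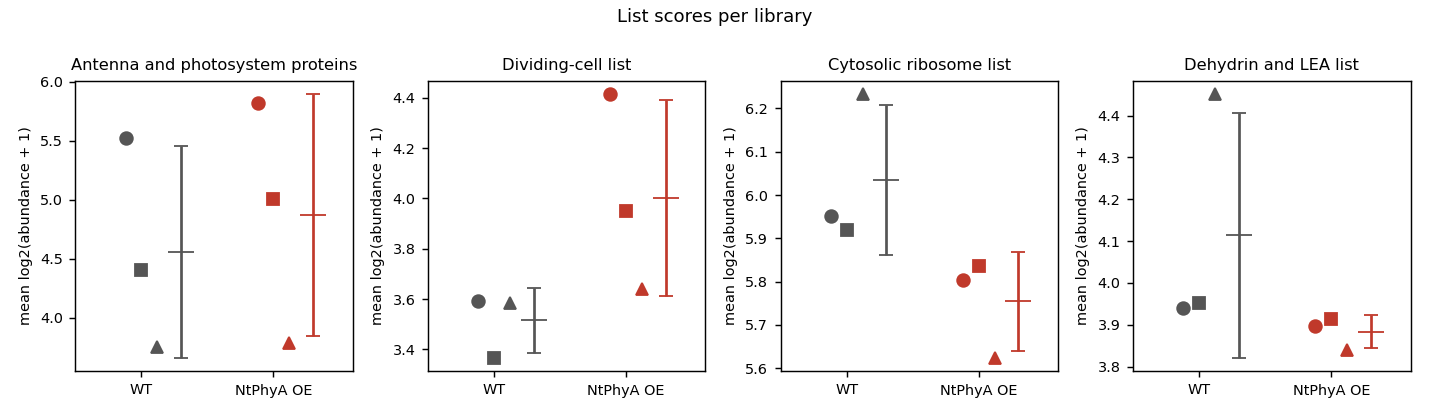
Mean log2(abundance + 1) over the members of 4 gene lists (vertical axes, each on its own scale and not starting at 0) in wild-type (grey) and NtPhyA overexpression (red) libraries. Circles, squares and triangles are replicates 1, 2 and 3, and bars show mean ± SD; dividing-cell scores average 3.52 and 4.00 and cytosolic ribosome scores 6.04 and 5.75, while the photosynthesis scores overlap.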

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

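The scalings, the surrogate variable, library weights, the fit without both replicates 3, and quantile normalization combined with the replicate block were chosen after seeing the data. The planned count-based forms (edgeR with other scalings, DESeq2 and limma-voom) were not run, since no counts were used. The single gene call stood at 1 with the stricter value filter, the fold minimum and upper-quartile scaling. It became 0 with a pseudocount of 0.1, no filter, an adjusted p below 0.01, equal totals, median-ratio scaling, quantile or scale normalization, the surrogate variable and without both replicates 3, and leaving out 1 library gave 0 to 0. limma gave 345 to 1464 genes at an unadjusted p below 0.05 in those settings. Library weights gave 9 calls, with a weight of 109 for overexpression replicate 2 and at most 1.07 for any other library. The estimation of the weights did not converge, so no weighted value here is reliable. With replicate number as a block there were 0 calls and 1183 genes at an unadjusted p below 0.05, also 0 with quantile normalization and the block. Deviations of replicates with the same number correlated at 0.56, -0.114 and 0.416, and not every library correlated best with its own number, so the numbers do not establish a pairing.

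The 10 list calls became 0 with an estimated correlation, 0 by fry and 3 with library weights, and 4 to 12 when 1 library was left out. With the replicate block there were 11. The difference in summed phytochrome log2 abundance was 0.29, from -0.222 to 0.778 when 1 library was left out and -0.0804 without both replicates 3. Under the alternatives, 1270 of 1290 values for 68 named genes and 621 of 665 list values kept their direction. No cause of the reversals was tested. The camera direction of some lists reversed, and their mean log2 differences in those settings follow. Without both replicates 3 they were 0.0248 (antioxidant enzymes), 0.0184 (proline and polyamines), 0.00555 (carbon fixation), 0.0534 (auxin), -0.114 (WRKY), 0.0697 (aquaporins) and 0.191 (phloem). With library weights they were -0.145 (proline and polyamines), 0.0101 (lipid desaturation), 0.00983 (auxin) and -0.135 (WRKY), and with equal totals 0.0781 (carbon fixation). With the replicate block they were -0.0332 (auxin) and -0.0417 (WRKY, also with the surrogate variable and by fry), and with quantile normalization and the block -0.0275 (auxin) and -0.033 (WRKY). The sign of the mean changed as well for antioxidant enzymes, aquaporins and carbon fixation. It also changed for auxin without both replicates 3 and with weights, and for proline and polyamines with weights. In the others the camera direction changed and the sign of the mean did not.

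Leaving out 1 library turned the camera direction in these lists, with mean log2 differences from -0.0744 to 0.318 (light signalling), -0.23 to 0.0494 (antioxidant enzymes), -0.292 to 0.0558 (glutathione S-transferases), -0.00473 to 0.252 (proline and polyamines), -0.179 to 0.686 (light harvesting), -0.223 to 0.248 (carbon fixation), -0.123 to 0.0567 (auxin), -0.261 to 0.11 (WRKY), -0.12 to 0.00345 (NAC and MYB), -0.0353 to 0.0146 (calcium), -0.411 to 0.124 (aquaporins), -0.0783 to 0.0138 (ubiquitin ligases), -0.132 to 0.203 (phloem), -0.0721 to 0.184 (guard cell), -0.328 to 0.0797 (flower) and -0.146 to 0.543 (organelle, with the mean also below 0 without wild-type replicate 3). The mean alone changed sign in the cell wall (-0.0594 to 0.0965) and pathogenesis-related (-0.0325 to 0.0866) lists. Of 266 values for the lists added later, 255 kept the camera direction. It turned with 1 library left out for antenna proteins (-0.159 to 0.856), plastocyanin-like proteins (-0.268 to 0.00638), AP2/ERF factors (-0.351 to 0.00191), B-box and CCT factors (-0.18 to 0.173; -0.0653 with weights) and secretory peroxidases (-0.244 to 0.0418). The direction also turned in phytochrome models Nitab4.5_0016503g0010 (-0.19 to 1.21; -0.13 without both replicates 3, -0.53 with weights) and Nitab4.5_0009346g0010 (-0.26 to 0.16), and in PsbR models Nitab4.5_0002475g0030 (-0.14 to 0.29) and Nitab4.5_0000313g0040 (-0.23 to 0.23). LEA-5, Nitab4.5_0002820g0100, went from -0.01 to between -0.31 and 0.53 with 1 library left out, 0.10 (equal totals), 0.053 (upper quartile), 0.013 (median ratio), 0.42 (without both replicates 3), 0.0202 (scale) and 0.31 (weights). The senescence regulator Nitab4.5_0006137g0010 was at 0.067 with weights. The shares of variance between groups were 16.8% and 16.6% under the 2 filters.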

Other observations

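The tests of the gene count over splits, depth, shared numbers, scaling, dividing cells and zero values below, and the 14 added lists, were chosen only after the result was seen. Dehydrins taken alone had 7 of 7 members lower under overexpression, with mean log2 abundances of 8.44 ± 0.47 in wild type and 7.56 ± 0.85 (SD, n = 3; exact two-sided permutation p = 0.3). The mean difference of -0.87 was -0.38 without overexpression replicate 3, and the call was lost. Ribosomal proteins of all compartments had 497 of 625 members lower, at 5.21 ± 0.15 and 4.98 ± 0.19 (SD, n = 3; exact two-sided permutation p = 0.2); their difference of -0.23 was -0.12 without overexpression replicate 3 and -0.14 without wild-type replicate 3, with the call kept. AP2/ERF factors, the family that includes the DREB-type CBF factors, had 93 of 144 members lower, and proteinase inhibitors 19 of 26. The AP2/ERF difference of -0.18 went to 0.00191 without wild-type replicate 3 and -0.01 without overexpression replicate 1, and its call was lost there and without overexpression replicate 2 (-0.185). That of proteinase inhibitors, -0.51, went to -0.15 without wild-type replicate 3 and -0.37 without overexpression replicate 1, both with the call lost. Two-component response regulators had 17 of 23 members higher, and their difference of 0.23 fell to 0.09 without overexpression replicate 3, with the call lost. The camera test with the preset correlation called 10 of these 14 lists, and 0 with an estimated correlation.

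With 3 libraries against 3 there are 10 splits of the 6 libraries, too few for a share under 0.05. The real split gave 1 called gene, 2 of the 10 splits gave at least as many, and the highest of the others gave 8. That split sets wild-type replicate 1 and overexpression replicates 1 and 2 against the rest and gave 3835 genes at an unadjusted p below 0.05, which points to a structure of the samples other than the plant material. For lists the real split gave 10, 5 of the 10 splits gave at least as many, and the highest of the others gave 17.

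Photosynthesis genes differed between libraries of 1 group. Over 144 antenna and photosystem genes, replicate 1 exceeded replicate 3 by a median of 1.68 log2 units in wild type and 1.95 under overexpression. Library depth is argued against as the whole cause. The lower quartile over these genes was 0.859 in wild type and 1.33 under overexpression, above the 0.421 log2 units between the deepest and the shallowest library. That bound comes from depth and does not limit other errors of normalization. Median-ratio scaling factors were 1.021 and 1.049 in wild-type replicates 1 and 3, and 1.053 and 0.9156 in overexpression replicates 1 and 3. A batch shared by replicates with the same number cannot be told apart from chance. Deviations correlated at 0.56 and 0.416 in 2 pairs but at -0.114 between the replicates numbered 2. Those lay between the others on the first principal component in both groups, so their low correlation says little about a shared batch. The labels give no further factor, and no biological explanation was tested.

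The dividing-cell list, mostly histones, had higher values in the overexpression libraries. The 4 scalings tried did not remove the difference. Equal totals, upper-quartile, median-ratio and quantile scaling left the list difference at 0.569, 0.534, 0.498 and 0.538 log2 units, against 0.486 unscaled. The lowest limit of the 95% intervals over libraries for the change they made was -0.155, where removing the difference needs a fall of 0.486. Factors of the equal-totals, upper-quartile and median-ratio scalings lay between 0.9156 and 1.198, too narrow for such a fall. That interval covers the change made by scaling, not the list difference, so it decides nothing further. Differences between the 2 tables that such scalings do not reach were not tested. The interval test replaced 2 earlier forms. The first, with the difference centred on all genes, could not respond to scaling. The second asked whether the 95% interval of the scaled difference excludes 0, which it does not under any of the 4 scalings, so chance between libraries stays open. Without overexpression replicate 1 the unscaled difference was 0.28.

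Whether more dividing cells explain these values stays open. Replication and mitosis genes other than histones had 17 of 22 members higher, with a preset camera adjusted p of 0.0118 (0.00583 to 0.686 over the alternatives) and no call with an estimated correlation (adjusted p = 0.48). Their difference of 0.184 ± 0.174 log2 units (SE) fell to 0.03 without wild-type replicate 3 and 0.13 without overexpression replicate 1, both with the call lost, too little against the spread to decide. An effect of the overexpression stays open too.

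Models at 0 in all libraries of 1 group, such as the ubiquitin-conjugating enzyme, numbered 20 where the other group was above 0.5 throughout. As many were found in 8 of the 9 other splits, up to 52, which is consistent with zero estimates that fall without regard to the group. This bears on the class of such genes and leaves the single called gene open.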
